A study of Mus musculus with 28 samples.

How the data were processed

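RNA of C57BL6/J mouse macrophages was measured on 28 single-colour 44K oligonucleotide arrays labelled with Cy3. Marrow cells were grown in CSF1 (200 ng/ml). From day 7 they received IL-4 (10 ng/ml) or IFN-γ (100 U/ml) for 18 h, with or without LPS (10 ng/ml) for the last 4 h. Cells of several animals were pooled, and the labels name 2 males and 1 female of 8 to 12 weeks. Replicates are named by experiment letters, with A to G for untreated and LPS, A, B, C and G for the IL-4 groups, and E, F and G for the IFN-γ groups.

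The deposited scanner files hold fluorescence intensities that Agilent Feature Extraction 9.5.1 produced, per the file headers. Within each array the signal was detrended and low spots were replaced by surrogates, without subtraction of the local background and without scaling between arrays. The authors also deposited a value table that the values show to be log2 differences from the probe's median over the columns named untreated. All 41174 of its probes have a median of 0 within 0.001 over these columns, whose order is in doubt as described in the closing section. Its column medians run from -0.266 to 0.59, and how it was scaled between arrays is not known. The scanner files were used throughout.

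The processed signal was log2 transformed, the array's 75th percentile was subtracted, and replicate spots of a probe were averaged. Spots the scanner software called outliers (at most 414 on an array) were left out, and at most 11 spots of an array were saturated. Of 41174 probes, 22951 were named through their transcript accession, 6659 through a current symbol and 3109 through a synonym, and 8455 kept the array's own name, which gave 27670 names. No genome came with the series, so no positions are given. A gene with several probes (8914 genes) was represented by its brightest. Among genes the naming rule covers, another probe moved in the opposite direction at unadjusted p under 0.05 for Itgb8 (IL-4 interaction), Slc2a3 (IL-4 alone) and Zbtb46 (both comparisons of IL-4 with IFN-γ). A gene was tested if its probe was well above background, by the scanner software's call, on at least 3 of the 28 arrays, which left 22446 genes. The number of arrays, 3 to 7 per group, limits the precision.

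All arrays entered 1 limma model of 6 group means (limma 3.58.1 in R 4.3.3, data.table version 1.17.8; figures with Python 3.11.15 and matplotlib 3.10.9). The 11 comparisons used limma's two-sided moderated test, with Benjamini-Hochberg adjustment over all genes of a comparison, and a gene was called at adjusted p under 0.05. An interaction is the LPS change in primed cells minus that in unprimed cells. After removal of group means, arrays of 1 letter correlated at 0.156 to 0.727 between the IL-4 groups and 0.277 to 0.635 between the IFN-γ groups. Letters paired arrays there, but not in the main model. Arrays of 1 slide set correlated at 0.391 to 0.727 between the IL-4 groups, so these letters stay in doubt. Between other groups some letter correlations were below 0.1. LPS-induced genes were selected at a log2 fold of at least 1 in experiments D, E and F for IL-4 and A to D for IFN-γ, and tested in the other experiments with adjustment over the selected genes. The overlap of the IL-4 and IFN-γ calls was set beside the count chance gives and 20 simulations of unchanged groups that share the untreated arrays.

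For 29 gene lists camera compared a list's genes with all others at a preset correlation of 0.01, adjusted over 319 tests. Results are given for 28 of the lists. Of 162 calls 72 hold with a correlation estimated from the data. The second p-value printed beside a call is the adjusted p with that estimate. Printed 95% intervals are not adjusted. List members called are counted over all genes and adjusted over the list alone. Some genes are in more than 1 list, and macrophages express many of the marker genes of other cell types.

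Named genes followed a rule. For each comparison these were the 12 largest rises and 12 largest falls among called genes that were above background in the brighter group. For each list they were up to 4 called members with the largest change and up to 2 furthest from passing. A fixed set of cytokine, chemokine and transcription factor genes was eligible everywhere. Some results the rule names are not given. Tgm2 in IL-4 against untreated falls outside the rule and was chosen after its value was seen. Where no array of the lower group was well above background, "at least N-fold" sets the mean of the brighter group against a floor. For each array of the lower group the floor is its lowest signal called well above background, or the gene's own signal where that is higher.

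The groups, comparisons, lists, named-gene rule and most alternatives were fixed before the data were examined. Alternatives fixed then were the experiment letter, slide or scan day as a block, only experiments with both groups, only the groups compared, normexp background correction (offset 50), quantile and median scaling, no filter or 14 arrays in the filter, the mean of all probes, and an intensity trend with robust variance. Each array and each experiment was also left out in turn, and other selection thresholds and a division of the untreated arrays were tried. Added later were the slide set, meaning a slide, or all slides of a scan day that has a single-array slide (10 slides in 7 sets on 5 days), as a block or in place of letters, the letter as a block within each primed arm, the data without slide set 5, and the value table with columns matched to scanner files.

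The procedure was tested on simulated data with planted changes in 22446 genes. For LPS against untreated 38% of genes planted at log2 1 and 78% at log2 2 were recovered, with 5 other genes called. For IFN-γ with LPS against IFN-γ 20% and 62% were recovered, for the IL-4 interaction 9% and 48%, and for the IFN-γ interaction 10% and 45%. Of 100 planted lowered LPS-induced genes 70 were selected and 69 called for IL-4, and 83 and 75 for IFN-γ.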

Results

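RNA from mouse bone marrow-derived macrophages, grown in the macrophage growth factor CSF1, was measured on 28 single-colour oligonucleotide arrays in 6 groups. Cells received no treatment (7 arrays), LPS for the last 4 h (7), IL-4 for 18 h (4), IL-4 with LPS (4), IFN-γ for 18 h (3) or IFN-γ with LPS (3). LPS is a bacterial cell wall component read by the receptor TLR4, IL-4 a cytokine of type 2 immunity and IFN-γ a cytokine of antiviral and antibacterial immunity. The 75th percentile of the scanner signal ran from 582 to 2113 intensity units over the arrays, and 60.3% to 78.7% of gene probes on an array were well above background. Arrays of a group correlated with one another at 0.940 to 0.991 across genes, which are not independent replicates. Changes of the 22446 tested genes are log2 fold changes ± standard error of the limma model. The words "at least" mark a bound. "Shared experiments" means only arrays whose letter is in all groups compared, though letters of untreated and LPS arrays are in doubt.

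LPS alone was set against no treatment (7 arrays each) to ask what the stimulus does to unprimed macrophages. The interleukin gene Il6 (at least 2565-fold) had the largest fitted rise, and the endothelin-1 gene Edn1 (12.87 ± 0.32), the prostaglandin synthase gene Ptgs2 (11.22 ± 0.40) and the cytokine genes Il1b (9.77 ± 0.45) and Il12b (8.92 ± 0.42) were among the next. The acute phase gene Saa3 (8.25 ± 0.32) and the inducible nitric oxide synthase gene Nos2 (8.24 ± 0.48) also rose. Among the largest falls were the cannabinoid receptor gene Cnr2 (-6.98 ± 0.41), Fam214a (-6.75 ± 0.41), the stress sensor gene Sesn1 (-5.46 ± 0.27) and the small GTPase gene Arl4c (-5.13 ± 0.25).

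Immune gene groups rose with LPS. Of the inflammatory cytokines, 27 rose and 1 fell of 29 (27 and 1 adjusted over the list alone, camera adjusted p = 1.27e-19, and 0.00197 with estimated correlation). For chemokines 21 rose and 0 fell of 24 (21 and 0 adjusted over the list alone, camera adjusted p = 1.77e-13, and 8.34e-04 with estimated correlation). These included Cxcl9 (8.05 ± 0.41), Cxcl3 (8.07 ± 0.51), Cxcl1 (6.12 ± 0.44) and Ccl5 (4.48 ± 0.19). In the type I interferon and antiviral group 37 rose and 0 fell of 38 (37 and 0 adjusted over the list alone, camera adjusted p = 8.34e-26, and 0.0247 with estimated correlation). Examples were Ifnb1 (4.80 ± 0.47) for interferon beta and the antiviral GTPase gene Mx1 (4.05 ± 0.20). Of genes for costimulation and coinhibition of T cells, 20 rose and 0 fell of 21 (20 and 0 adjusted over the list alone, camera adjusted p = 3.30e-15, and 0.00333 with estimated correlation). Among them were Slamf1 (7.22 ± 0.46) and Cd69 (7.12 ± 0.26). Among genes for TLR4 recognition and signalling 25 rose and 6 fell of 34 (26 and 6 adjusted over the list alone, camera adjusted p = 1.05e-08, and 0.0241 with estimated correlation). These included the adaptor kinase gene Ripk2 (4.61 ± 0.30) and the transcription factor gene Rel (4.06 ± 0.40). In the negative feedback group 23 rose and 5 fell of 32 (24 and 5 adjusted over the list alone, camera adjusted p = 2.18e-12, and 0.00399 with estimated correlation). The largest named were Socs3 (8.58 ± 0.25), the phosphatase gene Dusp2 (6.78 ± 0.20) and the ubiquitin editing gene Tnfaip3 (5.99 ± 0.17). MHC class I presentation had 17 rises and 0 falls among 18 (17 and 0 adjusted over the list alone, camera adjusted p = 1.88e-09, and 0.0582 with estimated correlation). They included the peptide transporter genes Tap1 (1.88 ± 0.17) and Tap2 (2.17 ± 0.15). For surface pattern recognition and scavenger receptors 19 rose and 5 fell of 32 (19 and 5 adjusted over the list alone), the formyl peptide receptor gene Fpr1 (6.32 ± 0.31) among them (camera adjusted p = 2.57e-06, and 0.0169 with estimated correlation).

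Groups outside immune signalling moved as well. In the arginine, nitric oxide and polyamine group 8 rose and 1 fell of 17 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00733, and 0.0218 with estimated correlation). Besides Nos2, Arg2 (4.58 ± 0.54) and Gch1 (3.35 ± 0.14) rose. With quantile normalization the group was not called, at adjusted p = 0.0661, and its median of 0.61 became 0.12. Proteases, coagulation and matrix genes had 20 rises and 2 falls among 33 (21 and 2 adjusted over the list alone, camera adjusted p = 5.77e-07, and 0.0025 with estimated correlation). Among them were Adamts4 (7.37 ± 0.51) and the proteoglycan gene Vcan (6.85 ± 0.31). In glycolysis and the hypoxia response 15 rose and 4 fell of 29 (16 and 4 adjusted over the list alone, camera adjusted p = 0.00171, and 0.254 with estimated correlation). These included the glycolytic regulator gene Pfkfb3 (4.84 ± 0.29). This call was lost with quantile normalization too, at adjusted p = 0.178. Of the cell cycle genes 0 rose and 30 fell of 37 (0 and 33 adjusted over the list alone, camera adjusted p = 9.16e-09, and 0.423 with estimated correlation). Examples were Gmnn (-3.43 ± 0.35), Cdc6 (-3.30 ± 0.32) and Bub1b (-3.28 ± 0.40). The class II activator gene Ciita (0.34 ± 0.34, adjusted p = 0.473) did not pass, with a 95% interval from -0.35 to 1.04.

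The limma model called 9500 genes, 4674 higher and 4826 lower, of which 2631 were at least 2-fold higher and 2929 at least 2-fold lower. With slide as a block 12942 genes were called, with scan day as a block 12131 and with normexp background correction 5545. Of the called genes 8571 (90.2%) had the same direction in each of 7 slide sets. The same arrays made the calls, so such shares are not replication.

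**Figure D1:**
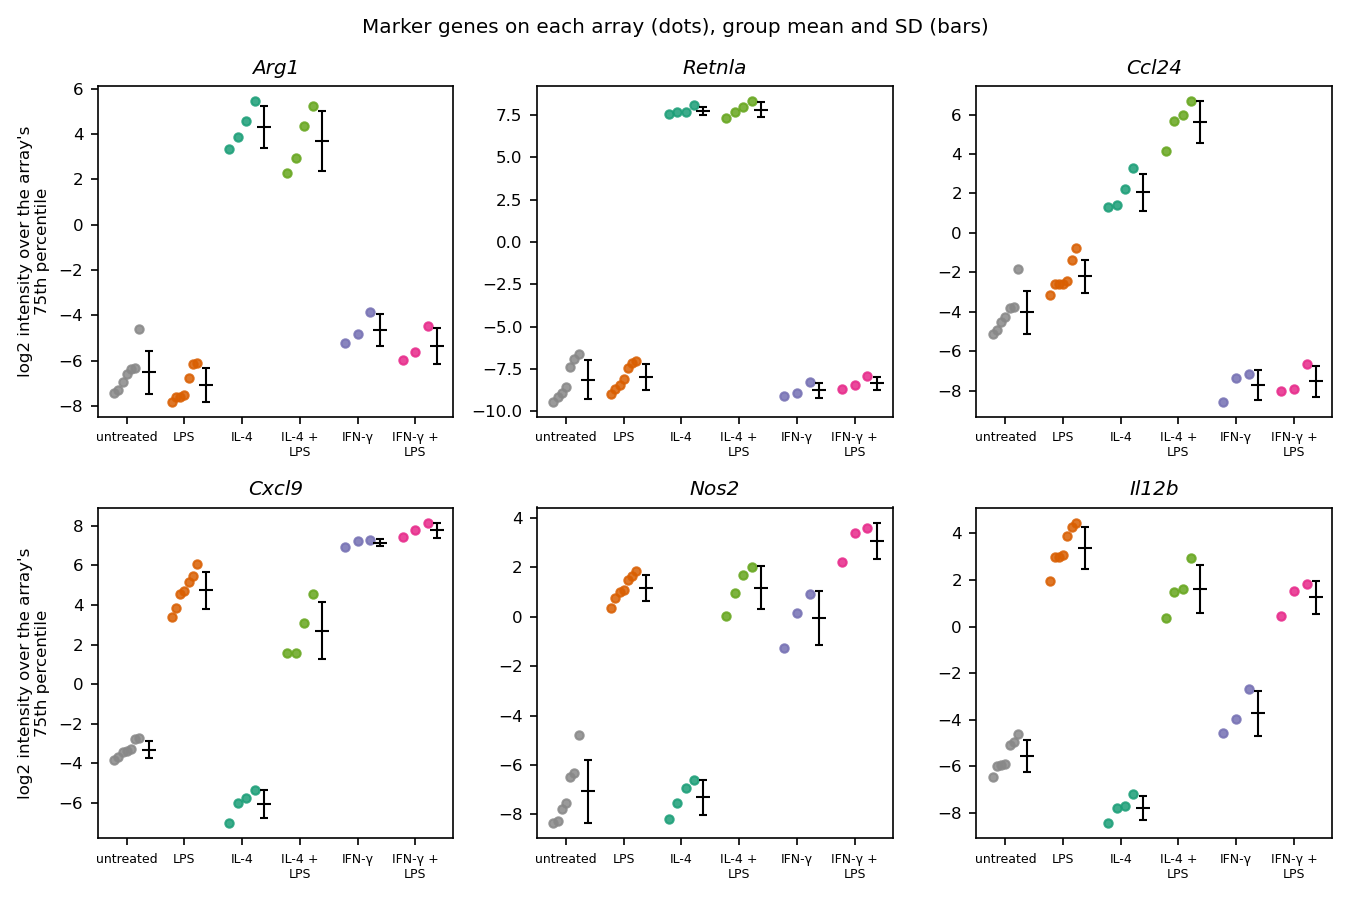
Dots give 6 genes on each of the 28 arrays, as log2 signal over the array's 75th percentile on the vertical axis, with bars for the group mean and SD. Retnla lies at 7.28 or above on the 8 arrays with IL-4 and at -6.60 or below on the others.

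IL-4 alone (4 arrays) was set against no treatment (7 arrays) to ask which genes mark the alternative form of macrophage activation. Retnla (at least 19572-fold), a secreted resistin-like protein gene, had the largest fitted rise. The arginase gene Arg1 (10.82 ± 0.55), the ribonuclease gene Rnase2a (8.66 ± 0.49), the water channel gene Aqp3 (8.06 ± 0.40), the lectin gene Mgl2 (6.71 ± 0.30) and the T cell inhibitory ligand gene Pdcd1lg2 (6.50 ± 0.55) were among the next. The fractalkine receptor gene Cx3cr1 (-5.72 ± 0.46) and the chemokine gene Cxcl10 (-4.80 ± 0.24) had large falls, as did the receptor genes Gpr84 (-4.48 ± 0.32), Pilrb1 (-4.47 ± 0.22) and Cd300e (-4.42 ± 0.32).

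Of the alternative activation and STAT6 target genes, 30 rose and 1 fell of 37 (32 and 1 adjusted over the list alone, camera adjusted p = 6.97e-50, and 8.69e-07 with estimated correlation). The fall was in the transglutaminase gene Tgm2 (-1.65 ± 0.21). Beyond the genes named, this group held the chemokine gene Ccl24 (6.10 ± 0.57), the chitinase-like gene Chil3 (3.95 ± 0.39) and the mannose receptor gene Mrc1 (1.72 ± 0.24). In the type I interferon and antiviral group 0 rose and 35 fell of 38 (0 and 37 adjusted over the list alone, camera adjusted p = 1.12e-51, and 0.00279 with estimated correlation). They included Ifit1 (-3.13 ± 0.24), Ifit3 (-3.77 ± 0.24) and Rsad2 (-3.14 ± 0.22). The feedback gene Socs1 (5.07 ± 0.22) rose. MHC class II presentation had 9 rises and 2 falls among 12 (9 and 2 adjusted over the list alone, camera adjusted p = 7.93e-07, and 0.109 with estimated correlation). Among them were the activator gene Ciita (2.48 ± 0.40) and the peptide loading genes H2-DMa (2.05 ± 0.24) and H2-DMb1 (1.73 ± 0.19). Of the surface pattern recognition receptors 5 rose and 14 fell of 32 (5 and 16 adjusted over the list alone, camera adjusted p = 4.25e-06, and 0.0188 with estimated correlation). Rises were seen in Clec7a (3.37 ± 0.39), the receptor for fungal glucan, and Olr1 (4.85 ± 0.61), and a fall in Clec4e (-3.28 ± 0.26). Olr1 was not called with normexp (1.37, adjusted p = 0.122). In the TLR4 group 1 rose and 11 fell of 34 (1 and 12 adjusted over the list alone, camera adjusted p = 1.44e-04, and 0.143 with estimated correlation). The LPS co-receptor gene Cd14 (-3.06 ± 0.18) fell. For chemokines 5 rose and 12 fell of 24 (7 and 12 adjusted over the list alone), Ccl8 (4.42 ± 0.33) rising beside Ccl24 (camera adjusted p = 0.0045, and 0.145 with estimated correlation). With slide set as a block this group was not called, at adjusted p = 0.0649. Among inflammatory cytokines 3 rose and 8 fell of 29 (3 and 10 adjusted over the list alone, camera adjusted p = 0.0263, and 0.443 with estimated correlation). Tnf (-2.49 ± 0.36) fell and Edn1 (6.65 ± 0.37) rose. This group was not called with scan day as a block, at adjusted p = 0.0741, or without untreated array G, at adjusted p = 0.0556. With normexp its median of -0.54 became 0.19 and it was not called, at adjusted p = 0.0967. Genes of oxidative phosphorylation, the mitochondrial energy pathway, had 28 rises and 0 falls among 30 (29 and 0 adjusted over the list alone, camera adjusted p = 2.83e-19, and 0.0218 with estimated correlation). These included Cyc1 (0.86 ± 0.16) and Uqcrfs1 (0.86 ± 0.20), the latter not called with normexp (adjusted p = 0.0892) or shared experiments (0.0584). The transcription factor genes Egr2 (4.99 ± 0.34), Batf3 (4.19 ± 0.29) and Irf4 (3.62 ± 0.34) rose. The gene of the IL-4 signal transducer, Stat6 (-0.21 ± 0.14, adjusted p = 0.446), and the chemokine gene Ccl22 (1.25 ± 0.60, adjusted p = 0.218) did not pass, with 95% intervals from -0.51 to 0.09 and 0.02 to 2.48.

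The limma model called 2531 genes (1292 higher, 1239 lower). There were 3057 with slide and 3926 with scan day as a block, 734 with normexp and 1524 with shared experiments. Of the called genes 2501 (98.8%) had the same direction in each of 4 slide sets.

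IFN-γ alone (3 arrays) was set against no treatment (7 arrays) to ask which genes mark classical priming. The guanylate-binding protein gene Gbp2b (10.51 ± 0.64) and the chemokine gene Cxcl9 (10.47 ± 0.53) had the largest measured rises, beside the ubiquitin-like gene Ubd (at least 507-fold). Ptgs2 (8.94 ± 0.51), the protease inhibitor genes Serpina3f (8.72 ± 0.41) and Serpina3g (8.08 ± 0.33), the nuclease gene Dnase1l3 (7.63 ± 0.47) and Nos2 (7.02 ± 0.62) followed. Falls included the transporter gene Slco2b1 (-7.12 ± 0.62), the lipid transporter gene Abca9 (at least 45.4-fold) and the haemoglobin scavenger receptor gene Cd163 (at least 15.9-fold), and the mannose receptor gene Mrc1 (-4.32 ± 0.27) also fell.

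For MHC class II 11 rose and 0 fell of 12 (11 and 0 adjusted over the list alone, camera adjusted p = 1.03e-14, and 0.012 with estimated correlation). Examples were Ciita (3.53 ± 0.44) and H2-Aa (2.73 ± 0.38). For MHC class I 17 rose and 0 fell of 18 (17 and 0 adjusted over the list alone, camera adjusted p = 1.49e-16, and 0.0112 with estimated correlation). They included Tap2 (2.03 ± 0.19) and Tapbpl (2.63 ± 0.21). In the type I interferon and antiviral group 33 rose and 0 fell of 38 (36 and 0 adjusted over the list alone, camera adjusted p = 4.96e-27, and 0.0218 with estimated correlation). Among them were Ifnb1 (4.56 ± 0.61) and Oasl1 (3.24 ± 0.27). Inflammatory cytokines had 17 rises and 1 fall among 29 (17 and 1 adjusted over the list alone, camera adjusted p = 8.20e-10, and 0.0188 with estimated correlation). These included Il1b (5.86 ± 0.58), Tnf (2.70 ± 0.39) and the activin gene Inhba (5.13 ± 0.34). Of the costimulation and coinhibition genes 14 rose and 1 fell of 21 (15 and 1 adjusted over the list alone, camera adjusted p = 2.02e-13, and 0.00485 with estimated correlation). Examples were Cd274 (4.84 ± 0.34), which encodes the inhibitory ligand PD-L1, and Cd40 (4.18 ± 0.20). In the negative feedback group 20 rose and 2 fell of 32 (21 and 2 adjusted over the list alone, camera adjusted p = 3.44e-14, and 0.0025 with estimated correlation). Socs1 (5.93 ± 0.24) and Socs3 (4.92 ± 0.33) rose and the IL-33 receptor gene Il1rl1 (-4.96 ± 0.49) fell. In the TLR4 group 16 rose and 1 fell of 34 (19 and 1 adjusted over the list alone, camera adjusted p = 1.53e-08, and 0.025 with estimated correlation). They included Traf1 (2.92 ± 0.18) and Ripk2 (2.76 ± 0.39). Chemokines had 9 rises and 5 falls among 24 (10 and 5 adjusted over the list alone), but this group was not called with slide as a block, at adjusted p = 0.0677, or without experiment G, at adjusted p = 0.0588 (camera adjusted p = 0.00141, and 0.0984 with estimated correlation). Among them were Cxcl10 (3.66 ± 0.27) and Ccl5 (4.19 ± 0.24).

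In glycolysis and the hypoxia response 23 rose and 2 fell of 29 (24 and 2 adjusted over the list alone, camera adjusted p = 1.76e-17, and 0.0025 with estimated correlation). These included Vegfa (4.17 ± 0.48), the glucose transporter gene Slc2a1 (3.01 ± 0.34) and Hk3 (2.69 ± 0.20). Oxidative phosphorylation had 11 rises and 0 falls among 30 (11 and 0 adjusted over the list alone), but the group's median of 0.33 became -0.04 with quantile normalization and it was not called without experiment G, at adjusted p = 0.0503 (camera adjusted p = 1.42e-05, and 0.307 with estimated correlation). Examples were Cycs (1.88 ± 0.25) and Cox5a (1.15 ± 0.16). Of the cell cycle genes 1 rose and 23 fell of 37 (3 and 31 adjusted over the list alone, camera adjusted p = 3.38e-08, and 0.448 with estimated correlation). They included falls in Kif20a (-3.43 ± 0.56) and Cdc20 (-3.38 ± 0.55). Of the alternative activation genes 12 rose and 12 fell of 37 (12 and 12 adjusted over the list alone), and the group was not called (camera adjusted p = 0.96). Cish (4.88 ± 0.66) and Flt1 (4.68 ± 0.36) rose and F13a1 (-4.76 ± 0.53) fell.

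The limma model called 5803 genes (2841 higher, 2962 lower). Blocking by slide gave 7444, blocking by scan day 7152 and normexp 2682, and 5578 of the called genes (96.1%) had the same direction in each of 3 slide sets. Without experiment E 3680 genes were called. The median over all genes was -0.286 and became 0.161 with median scaling, under which 77.8% of called genes were higher in place of 49.0%.

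**Figure D2:**
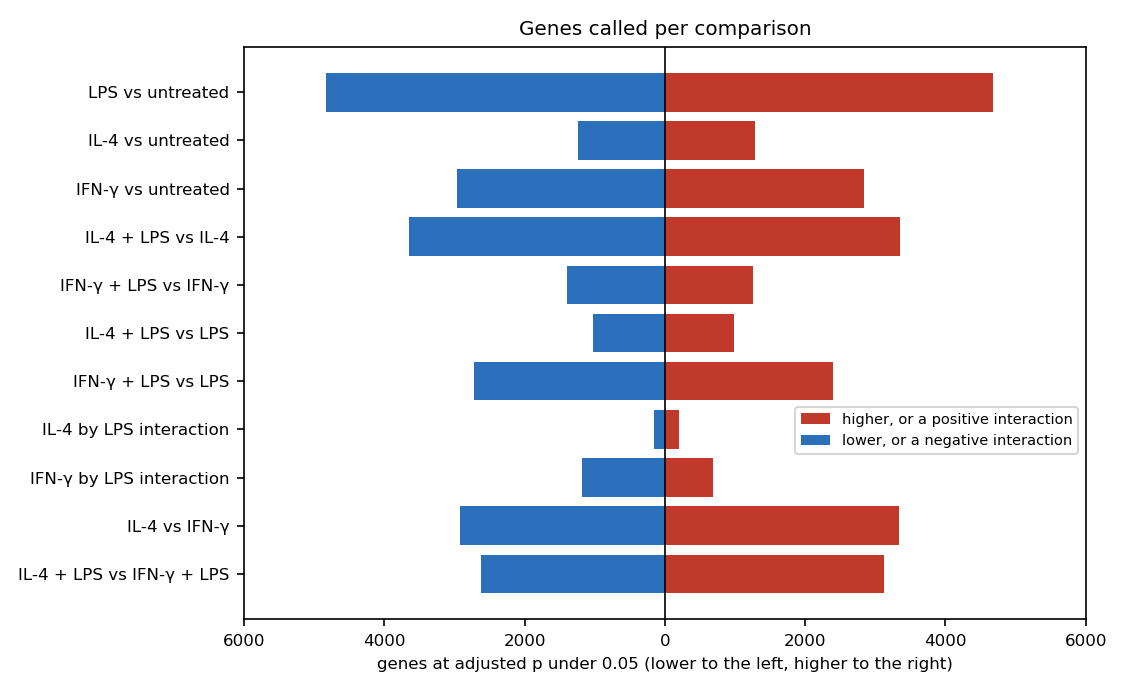
Bars give the number of genes at adjusted p under 0.05 in each of the 11 comparisons, lower to the left and higher to the right of 0, with positive and negative values for the 2 interactions. LPS alone against no treatment has 4674 genes to the right and 4826 to the left.

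IL-4 (4 arrays) and IFN-γ (3 arrays) were set against each other to ask where the 2 priming states part. Mgl2 (9.89 ± 0.37), Arg1 (8.95 ± 0.68), Aqp3 (8.84 ± 0.49) and Ccl24 (at least 479-fold) were higher with IL-4. Cxcl9 (-13.19 ± 0.59), Gbp2b (-10.23 ± 0.71), Clic5 (-8.68 ± 0.46), Cxcl10 (-8.46 ± 0.30) and the itaconate synthase gene Acod1 (-8.27 ± 0.24) were lower with IL-4, that is, higher with IFN-γ. Of the alternative activation genes 27 were higher and 2 lower of 37 (31 and 3 adjusted over the list alone, camera adjusted p = 1.80e-18, and 4.21e-04 with estimated correlation). Of the antiviral genes 0 were higher and 37 lower of 38 (0 and 37 adjusted over the list alone, camera adjusted p = 3.43e-49, and 0.00333 with estimated correlation). Among them were Isg20 (-5.47 ± 0.24) and Rsad2 (-5.69 ± 0.26). MHC class I genes had 0 higher and 16 lower of 18 (0 and 17 adjusted over the list alone, camera adjusted p = 6.95e-14, and 0.0188 with estimated correlation). MHC class II genes had 0 higher and 8 lower of 12 (0 and 10 adjusted over the list alone, camera adjusted p = 8.81e-06, and 0.154 with estimated correlation). In glycolysis and the hypoxia response 1 was higher and 22 lower of 29 (1 and 22 adjusted over the list alone, camera adjusted p = 7.59e-15, and 0.00442 with estimated correlation). For inflammatory cytokines 2 were higher and 17 lower of 29 (2 and 18 adjusted over the list alone, camera adjusted p = 6.31e-09, and 0.0247 with estimated correlation). Of the cell cycle genes 23 were higher and 0 lower of 37 (30 and 2 adjusted over the list alone, camera adjusted p = 6.64e-07, and 0.494 with estimated correlation). Surface receptors had 8 higher and 16 lower of 32 (8 and 17 adjusted over the list alone, camera adjusted p = 2.11e-04, and 0.0568 with estimated correlation). Mrc1 (6.04 ± 0.30) was higher with IL-4 and Fpr2 (-7.56 ± 0.43) and Clec4e (-6.10 ± 0.32) lower. Ptgs1 (7.18 ± 0.54) and Il1rl1 (6.92 ± 0.54) were higher and Cd86 (-4.17 ± 0.36) lower.

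In all 6260 genes were called (3334 higher with IL-4, 2926 lower), 5022 with the experiment letter as a block, 7053 with slide, 7006 with scan day and 3065 with normexp. The groups share only 1 slide set. The median over all genes was 0.301, and -0.061 with median scaling, under which 27.6% of called genes were higher with IL-4 in place of 53.3%.

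The calls of the 2 priming comparisons overlapped in 1267 genes. Of these 577 changed in the same direction and 690 in opposite directions. Both rose for 300 genes (164 by chance) and both fell for 277 (164), while 260 rose with IL-4 and fell with IFN-γ (170) and 430 fell with IL-4 and rose with IFN-γ (157). Ciita, Socs1 and Cish, a feedback gene of cytokine receptors, rose in both, and Cx3cr1 fell in both, while Mrc1 and Irf4 rose with IL-4 and fell with IFN-γ. The changes correlated at 0.03 across genes, which are not independent replicates, and the shared untreated arrays alone gave 0.33 in simulated unchanged groups, in which no gene overlapped (mean of 20 simulations 0). With the untreated arrays divided between the 2 comparisons 782 genes overlapped, 336 in the same and 446 in opposite directions.

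In IL-4-primed cells LPS (4 arrays each) raised Il1b (12.58 ± 0.59), Il6 (12.40 ± 0.63), Ptgs2 (at least 3335-fold), Fpr2 (9.55 ± 0.40) and the chemokine gene Cxcl2 (9.15 ± 0.51), all among the 12 largest rises. It lowered Cnr2 (-6.32 ± 0.54), Fam214a (-6.12 ± 0.54), Plekhg3 (-5.35 ± 0.40) and Cxcr4 (-4.72 ± 0.45). Of the inflammatory cytokines 27 rose and 1 fell of 29 (27 and 1 adjusted over the list alone, camera adjusted p = 8.37e-25, and 5.85e-04 with estimated correlation). Of the chemokines 20 rose and 0 fell of 24 (20 and 0 adjusted over the list alone, camera adjusted p = 2.31e-18, and 3.53e-04 with estimated correlation). Examples were Ccl17 (8.03 ± 0.50) and Ccl22 (7.71 ± 0.67). Of the antiviral genes 37 rose and 0 fell of 38 (37 and 0 adjusted over the list alone, camera adjusted p = 4.14e-43, and 0.00485 with estimated correlation). They included Cmpk2 (6.45 ± 0.29) and Rsad2 (6.28 ± 0.24). For costimulation genes 18 rose and 0 fell of 21 (19 and 0 adjusted over the list alone, camera adjusted p = 3.92e-18, and 0.00197 with estimated correlation). Among them were Cd69 (8.58 ± 0.35) and the adhesion gene Vcam1 (7.08 ± 0.38). For negative feedback 21 rose and 5 fell of 32 (22 and 5 adjusted over the list alone, camera adjusted p = 5.40e-11, and 0.00578 with estimated correlation). These included Nfkbiz (7.83 ± 0.37) and Il1rn (6.30 ± 0.39), the IL-1 receptor antagonist. Cell cycle genes had 0 rises and 30 falls among 37 (0 and 33 adjusted over the list alone, camera adjusted p = 2.98e-11, and 0.326 with estimated correlation). The IL-4 markers Arg1 (-0.60 ± 0.63, adjusted p = 0.548) and Chil3 (0.03 ± 0.44, adjusted p = 0.978) did not pass with LPS, with 95% intervals from -1.89 to 0.69 and -0.88 to 0.93. In all 7001 genes were called (3357 higher, 3644 lower). Slide as a block gave 11591, scan day 9741 and normexp 3568, and 98.5% of called genes had the same direction in each of 4 slide sets.

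In IFN-γ-primed cells LPS (3 arrays each) raised Cxcl1 (7.82 ± 0.66), Il1a (7.44 ± 0.79), the transcriptional repressor gene Gfi1 (7.16 ± 0.59), Il6 (6.83 ± 0.73) and Edn1 (6.59 ± 0.48), all among the 12 largest rises, and lowered Fam78a (-3.86 ± 0.40), Fbxo31 (-3.10 ± 0.39) and Lpar6 (-3.31 ± 0.37). Of the inflammatory cytokines 22 rose and 0 fell of 29 (24 and 0 adjusted over the list alone, camera adjusted p = 2.45e-27, and 4.21e-04 with estimated correlation). They included Il10 (5.08 ± 0.32) and Il12b (4.99 ± 0.64). Of the chemokines 9 rose and 0 fell of 24 (9 and 0 adjusted over the list alone, camera adjusted p = 7.31e-09, and 0.00455 with estimated correlation). Among them were Ccl3 (4.76 ± 0.39) and Cxcl3 (4.95 ± 0.77), the latter not called with normexp (adjusted p = 0.0502). Costimulation genes had 16 rises and 0 falls among 21 (17 and 0 adjusted over the list alone, camera adjusted p = 1.49e-16, and 0.0025 with estimated correlation). These included Slamf1 (5.27 ± 0.70) and Tnfsf9 (4.39 ± 0.56). Negative feedback genes had 19 rises and 2 falls among 32 (21 and 3 adjusted over the list alone, camera adjusted p = 2.09e-18, and 8.25e-04 with estimated correlation). Of the antiviral genes 13 rose and 0 fell of 38 (19 and 0 adjusted over the list alone, camera adjusted p = 3.68e-10, and 0.211 with estimated correlation). With normexp their median of 0.62 became 0.22 and they were not called, at adjusted p = 0.751. The chemokine genes Cxcl9 (0.63 ± 0.63, adjusted p = 0.668) and Cxcl10 (0.51 ± 0.32, adjusted p = 0.385) did not pass, with 95% intervals from -0.67 to 1.93 and -0.14 to 1.17. In all 2658 genes were called (1260 higher, 1398 lower). The count was 6951 with slide and 5206 with scan day as a block, 865 with normexp, 1394 with median scaling, 1478 with shared experiments and 750 (474 higher, 276 lower) with only the groups compared. Of the called genes 99.8% had the same direction in each of 3 slide sets. Fewer were called without experiment E (1443), experiment F (1297), IFN-γ array G (1748) or IFN-γ with LPS array E (1718).

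IL-4 with LPS (4 arrays) was set against LPS alone (7 arrays) to ask what IL-4 priming leaves in cells that then meet LPS. The IL-4 markers Retnla (at least 15552-fold) and Arg1 (at least 898-fold) and the genes Rnase2a (8.20 ± 0.49), Ccl24 (7.84 ± 0.57), Mgl2 (6.86 ± 0.30), Pdcd1lg2 (6.00 ± 0.55) and fibronectin, Fn1 (5.51 ± 0.50), were higher in primed cells. Cd300e (-4.25 ± 0.32), the costimulatory receptor gene Tnfrsf9 (-3.59 ± 0.47), Cx3cr1 (-3.30 ± 0.46) and the chemokine gene Cxcl11 (-3.04 ± 0.34) were lower. The inflammatory genes Tnf (0.05 ± 0.36, adjusted p = 0.968), Il1b (0.59 ± 0.53, adjusted p = 0.654) and Nos2 (0.01 ± 0.56, adjusted p = 0.997) did not pass, with 95% intervals from -0.69 to 0.78, -0.49 to 1.68 and -1.15 to 1.16. Il6 (1.59 ± 0.56, adjusted p = 0.0806) passed only with slide as a block (1.56, adjusted p = 0.0339), with scan day (1.71, adjusted p = 0.0435) or slide set as a block (1.71, adjusted p = 0.0167) and with quantile normalization (1.49, adjusted p = 0.0394).

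Of the alternative activation genes 28 were higher and 2 lower of 37 (31 and 2 adjusted over the list alone, camera adjusted p = 3.29e-44, and 1.32e-06 with estimated correlation). For MHC class II 9 were higher and 0 lower of 12 (9 and 0 adjusted over the list alone, camera adjusted p = 2.14e-11, and 0.0257 with estimated correlation). They included Ciita (2.70 ± 0.40) and H2-DMa (2.01 ± 0.24). The inflammatory cytokines divided, with 6 higher and 5 lower of 29 (8 and 8 adjusted over the list alone, camera adjusted p = 0.882). Il12a (3.80 ± 0.50) and Hbegf (4.00 ± 0.42) were higher and Il10 (-1.45 ± 0.25) lower. Antiviral genes had 0 higher and 4 lower of 38 (0 and 8 adjusted over the list alone, camera adjusted p = 2.14e-08, and 0.281 with estimated correlation), with Isg20 (-1.20 ± 0.20) lower. In glycolysis and the hypoxia response 2 were higher and 10 lower of 29 (2 and 13 adjusted over the list alone, camera adjusted p = 3.20e-04, and 0.18 with estimated correlation). Pfkfb3 (-1.82 ± 0.34) and Bnip3 (-1.53 ± 0.30) were lower and the carbonic anhydrase gene Car4 (2.62 ± 0.61) higher. Car4 (1.04, adjusted p = 0.915) and Cx3cr1 (-1.78, 0.0817) were not called with normexp. Oxidative phosphorylation had 9 higher and 0 lower of 30 (22 and 0 adjusted over the list alone, camera adjusted p = 2.13e-10, and 0.112 with estimated correlation). The chemokine genes Ccl17 (5.33 ± 0.45) and Ccl22 (3.78 ± 0.60) and the transcription factor genes Irf4 (3.80 ± 0.34) and Batf3 (3.93 ± 0.29) were higher.

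In all 2011 genes were called (980 higher, 1031 lower), 3835 with slide and 3225 with scan day as a block. There were 533 with normexp, 1103 with median scaling, 1231 with shared experiments and 1154 with only the groups compared. Within slide sets 98.3% of called genes had the same direction in each of 4, and with median scaling 37.4% of called genes were higher in place of 48.7%. Without experiment A 1139 genes were called.

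IFN-γ with LPS (3 arrays) was set against LPS alone (7 arrays) to ask what IFN-γ priming adds to LPS. Ubd (10.47 ± 0.74), Gbp2b (6.48 ± 0.64), Dnase1l3 (5.74 ± 0.47), Vegfa (5.60 ± 0.48), the lipid droplet gene Hilpda (5.12 ± 0.56) and the IL-12 receptor gene Il12rb1 (4.86 ± 0.30) were higher. The cytokine gene Il19 (-5.81 ± 0.62), the metallothionein gene Mt2 (-5.64 ± 0.36), Cbr2 (-5.53 ± 0.30) and the leukotriene enzyme gene Alox5 (-4.74 ± 0.67) were lower, as were Mrc1 (-4.15 ± 0.27) and Ccl17 (-3.61 ± 0.49).

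For MHC class II 10 were higher and 0 lower of 12 (12 and 0 adjusted over the list alone, camera adjusted p = 1.27e-16, and 0.00806 with estimated correlation). Among them were Ciita (3.84 ± 0.44) and H2-Aa (2.46 ± 0.38). The chemokine gene Cxcl9 (3.04 ± 0.53) was higher. Of the inflammatory cytokines 7 were higher and 7 lower of 29 (9 and 8 adjusted over the list alone), with a median of -0.10 and a mean of 0.16 (camera adjusted p = 0.583). Il23a (4.23 ± 0.67) and Inhba (3.08 ± 0.34) were higher beside Vegfa, and Il19 lower. Il23a (1.98, adjusted p = 0.0781) and Ccl17 (-1.73, 0.0631) were not called with normexp. In glycolysis and the hypoxia response 19 were higher and 1 lower of 29 (20 and 2 adjusted over the list alone, camera adjusted p = 1.81e-12, and 0.00831 with estimated correlation). Examples were Egln3 (2.97 ± 0.53), Bnip3 (2.93 ± 0.33) and Slc2a1 (2.15 ± 0.34). Costimulation genes had 6 higher and 0 lower of 21 (9 and 1 adjusted over the list alone, camera adjusted p = 6.41e-04, and 0.19 with estimated correlation). They included Slamf8 (4.28 ± 0.28) and Cd86 (1.58 ± 0.32). Negative feedback genes had 10 higher and 2 lower of 32 (10 and 2 adjusted over the list alone, camera adjusted p = 2.94e-04, and 0.117 with estimated correlation). Among them was Il1r2 (3.63 ± 0.36), the IL-1 decoy receptor. With normexp the median of 0.36 became 0.18 and the group was not called, at adjusted p = 0.211. For surface receptors 2 were higher and 12 lower of 32 (2 and 16 adjusted over the list alone, camera adjusted p = 0.0038, and 0.143 with estimated correlation), with the scavenger receptor gene Stab1 (-3.03 ± 0.39) lower. Cell cycle genes had 3 higher and 16 lower of 37 (4 and 19 adjusted over the list alone, camera adjusted p = 0.00419, and 0.714 with estimated correlation). Ccnd1 (2.73 ± 0.57) and Ccne1 (2.66 ± 0.41) were higher and Ccnb1 (-2.31 ± 0.50) and Ccnb2 (-2.61 ± 0.43) lower. The group was not called without IFN-γ with LPS array F, at adjusted p = 0.0661, without LPS array B, at adjusted p = 0.0516, or with shared experiments, at adjusted p = 0.0677. Il6 (-0.64 ± 0.61, adjusted p = 0.51), Il1b (0.65 ± 0.58, adjusted p = 0.473) and Il10 (-0.35 ± 0.27, adjusted p = 0.41) did not pass, with 95% intervals from -1.90 to 0.63, -0.54 to 1.84 and -0.91 to 0.22.

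In all 5109 genes were called (2392 higher, 2717 lower). Slide as a block gave 7595, scan day 6838, normexp 2042 and shared experiments 2430, and 97.5% of called genes had the same direction in each of 3 slide sets. Without experiment E 2946, without experiment F 2914 and without IFN-γ with LPS array E 3214 genes were called. The median over all genes was -0.234, and 0.036 with median scaling, under which 72.6% of called genes were higher in place of 46.8%.

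Whether IL-4 changes the LPS response was tested as an interaction over 22 arrays. The LPS change was more positive after IL-4 for Cxcl10 (4.58 ± 0.34), Il12a (4.28 ± 0.71), Ccl17 (4.20 ± 0.63) and Cxcl2 (4.11 ± 0.64). It was more negative for Edn1 (-5.95 ± 0.53), Socs1 (-4.51 ± 0.31) and the amino acid oxidase gene Il4i1 (-3.28 ± 0.48). In the antiviral group 20 had a positive and 0 a negative interaction of 38 (31 and 0 adjusted over the list alone, camera adjusted p = 1.38e-56, and 0.00217 with estimated correlation). These included Rsad2 (2.92 ± 0.31), Ifit3 (2.87 ± 0.34) and Ifit1 (2.70 ± 0.34). Of the chemokines 7 had a positive and 0 a negative interaction of 24 (11 and 1 adjusted over the list alone, camera adjusted p = 9.28e-11, and 0.0025 with estimated correlation). Surface receptors had 4 positive and 0 negative interactions of 32 (6 and 1 adjusted over the list alone, camera adjusted p = 1.88e-04, and 0.0545 with estimated correlation). Examples were Clec4e (2.94 ± 0.37) and Fpr2 (3.47 ± 0.50). Of the alternative activation genes 1 had a positive and 5 a negative interaction of 37 (3 and 8 adjusted over the list alone, camera adjusted p = 2.04e-04, and 0.0722 with estimated correlation), with Klf4 (-2.95 ± 0.42) and Egr2 (-2.58 ± 0.48) negative. With normexp Edn1 (-2.16, adjusted p = 0.398), Il12a (2.73, 0.241), Cxcl2 (1.40, 1) and Fpr2 (0.96, 1) were not called. With shared experiments Cxcl2 (3.74, 0.0542) and Egr2 (-2.25, 0.0778) were not. In all 356 genes were called (203 positive, 153 negative). Slide as a block gave 1062 and scan day 905, while normexp gave 40, shared experiments 107 and median scaling 184. Of the called genes 99.4% had the same direction in each of 4 slide sets. Leaving out experiment A, B or C gave 149, 182 and 168. Across 5560 genes changed at least 2-fold by LPS alone the responses with and without IL-4 correlated at 0.94, with a median ratio of 0.91 and the same sign for 98.2%; these genes were chosen on the same LPS and untreated arrays.

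Genes at least 2-fold higher in LPS than in untreated arrays of experiments D, E and F were tested in the others. Of 5125 such genes, 214 were lower and 118 higher with IL-4 and LPS than with LPS alone, and the LPS change was smaller for 57 and larger for 108. Without LPS array A these counts were 133 lower, 31 smaller and 71 larger, and without LPS array G 140, 32 and 61. Without untreated array C 33 were smaller, and without IL-4 array G or IL-4 with LPS array C 66 and 64 larger. With slide sets in place of letters 2870 were selected (245 lower, 100 higher), with a median difference of -0.24 in place of 0.28.

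The same interaction for IFN-γ was tested over 20 arrays. The LPS change was more negative after IFN-γ for Cxcl9 (-7.42 ± 0.75), Ptgs2 (-6.85 ± 0.73), Edn1 (-6.28 ± 0.58), Cxcl11 (-6.03 ± 0.53), Il1b (-5.21 ± 0.82), Socs1 (-5.13 ± 0.34) and Nos2 (-5.12 ± 0.87). It was more positive for the transcription factor gene Irf4 (4.47 ± 0.53), and for Fam214a (4.74 ± 0.75), Cnr2 (4.24 ± 0.75) and Arl4c (4.20 ± 0.46), which LPS alone lowered. Of the antiviral genes 0 had a positive and 29 a negative interaction of 38 (0 and 36 adjusted over the list alone, camera adjusted p = 3.52e-38, and 0.00786 with estimated correlation). They included Cmpk2 (-3.23 ± 0.40) and Mx1 (-2.63 ± 0.37). For inflammatory cytokines 1 had a positive and 13 a negative interaction of 29 (1 and 13 adjusted over the list alone, camera adjusted p = 1.92e-09, and 0.0212 with estimated correlation). The positive one was the IL-23 subunit gene Il23a. Chemokines had 0 positive and 9 negative interactions of 24 (0 and 9 adjusted over the list alone, camera adjusted p = 2.73e-09, and 0.00399 with estimated correlation). Among them were Ccl8 (-5.94 ± 0.52) and Ccl12 (-4.28 ± 0.73). Costimulation genes had 0 positive and 10 negative interactions of 21 (0 and 12 adjusted over the list alone, camera adjusted p = 1.05e-10, and 0.0117 with estimated correlation). These included Cd40 (-3.64 ± 0.28) and Cd274 (-3.37 ± 0.49). Negative feedback genes had 2 positive and 14 negative interactions of 32 (4 and 14 adjusted over the list alone, camera adjusted p = 2.35e-09, and 0.0112 with estimated correlation). Examples were Socs3 (-4.57 ± 0.46) and Il1rn (-3.99 ± 0.54). In MHC class I 0 had a positive and 10 a negative interaction of 18 (0 and 11 adjusted over the list alone, camera adjusted p = 1.01e-11, and 0.0316 with estimated correlation). They included Tap2 (-1.81 ± 0.27) and Tapbpl (-1.89 ± 0.29). For proteases, coagulation and matrix 1 had a positive and 8 a negative interaction of 33 (1 and 11 adjusted over the list alone, camera adjusted p = 4.89e-06, and 0.00435 with estimated correlation). Among them was Vcan (-5.48 ± 0.57). Nos2 was not called with normexp (-1.56, adjusted p = 0.465), nor with shared experiments were Nos2 (-5.20, 0.0527) and Il1b (-4.87, 0.054). Tnf (-1.25 ± 0.56, adjusted p = 0.215) did not pass, with a 95% interval from -2.40 to -0.10. In all 1865 genes were called (680 positive, 1185 negative). Slide as a block gave 4153 and scan day 3660, while normexp gave 748, shared experiments 622 and median scaling 1043. Of the called genes 98.9% had the same direction in each of 3 slide sets. Without experiment E 819 and without experiment F 1031 genes were called. With median scaling 25.4% and with normexp 18.3% of called interactions were positive in place of 36.5%. Across the same 5560 genes the responses with and without IFN-γ correlated at 0.85, with a median ratio of 0.485 and the same sign for 92.7%.

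Of 2262 genes that LPS raised at least 2-fold in experiments without IFN-γ, 449 were lower and 179 higher with IFN-γ and LPS than with LPS alone in the others. The LPS change was smaller for 952 and larger for 9. The median interaction was -1.10, and the median of IFN-γ with LPS minus LPS alone was -0.29. Without IFN-γ with LPS array E 287 were lower and 107 higher, without array F of that group 100 were higher, without LPS array E 280 were lower, and without LPS arrays F or G 109 and 119 were higher. The 9 larger changes fell to 3 without LPS array G and 5 without any 1 of 4 other arrays. With slide sets in place of letters 2525 genes were selected, 1009 with a smaller and 10 with a larger change.

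**Figure D3:**
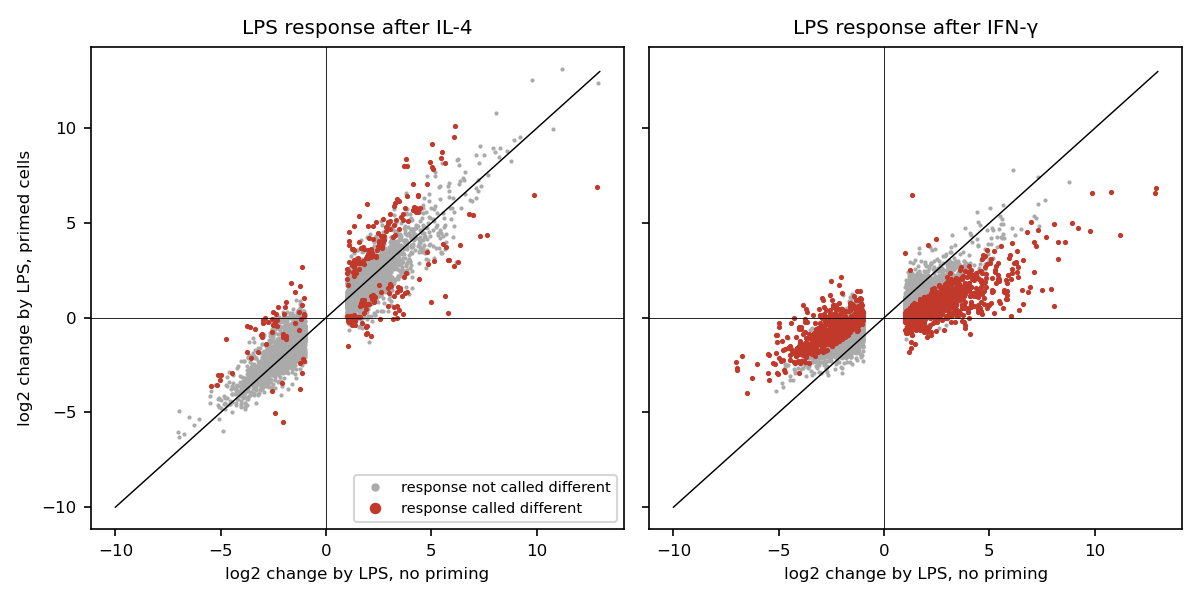
Each dot is 1 of 5560 genes changed at least 2-fold by LPS alone, with its log2 LPS change in unprimed cells on the horizontal axis and in cells primed with IL-4 (left) or IFN-γ (right) on the vertical axis; red dots have an interaction at adjusted p under 0.05 and the line marks equal changes.

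The 2 priming states were also compared after LPS (4 arrays with IL-4, 3 with IFN-γ). Ccl24 (at least 4078-fold) was higher with IL-4, as were Mgl2 (9.29 ± 0.37), Arg1 (9.05 ± 0.68), Ccl17 (8.94 ± 0.54) and Mt2 (6.65 ± 0.40). Vegfa (-6.89 ± 0.53), Cxcl11 (-5.56 ± 0.42), Cxcl9 (-5.08 ± 0.59), the complement protease gene C1s1 (-5.67 ± 0.30) and the growth factor gene Pdgfb (-5.24 ± 0.41) were lower with IL-4. Of the alternative activation genes 27 were higher and 2 lower of 37 (28 and 3 adjusted over the list alone, camera adjusted p = 3.92e-18, and 4.29e-04 with estimated correlation). In glycolysis and the hypoxia response 1 was higher and 22 lower of 29 (2 and 22 adjusted over the list alone, camera adjusted p = 3.36e-15, and 0.00416 with estimated correlation). MHC class II genes had 0 higher and 6 lower of 12 (0 and 9 adjusted over the list alone, camera adjusted p = 7.41e-05, and 0.215 with estimated correlation). Negative feedback genes had 3 higher and 13 lower of 32 (3 and 17 adjusted over the list alone, camera adjusted p = 1.81e-05, and 0.0586 with estimated correlation), with Il1r2 (-2.62 ± 0.40) lower and Il1rl1 (4.05 ± 0.54) higher. In the arginine group 5 were higher and 4 lower of 17 (6 and 4 adjusted over the list alone, camera adjusted p = 0.645). Arg1 and the spermidine synthase gene Srm (2.96 ± 0.66) were higher. Cd14 (-1.99 ± 0.22) was lower with IL-4, and Il1b (-0.06 ± 0.64, adjusted p = 0.952) and Cxcl10 (-0.60 ± 0.30, adjusted p = 0.145) did not pass, with 95% intervals from -1.38 to 1.26 and -1.22 to 0.01. In all 5736 genes were called (3120 higher with IL-4, 2616 lower), 4441 with the experiment letter as a block, 6799 with slide, 6530 with scan day, 2491 with normexp and 2472 with only the groups compared. The median over all genes was 0.294, and -0.032 with slide set as a block. It was -0.082 with median scaling, under which 25.3% of called genes were higher in place of 54.4%.

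**Figure D4:**
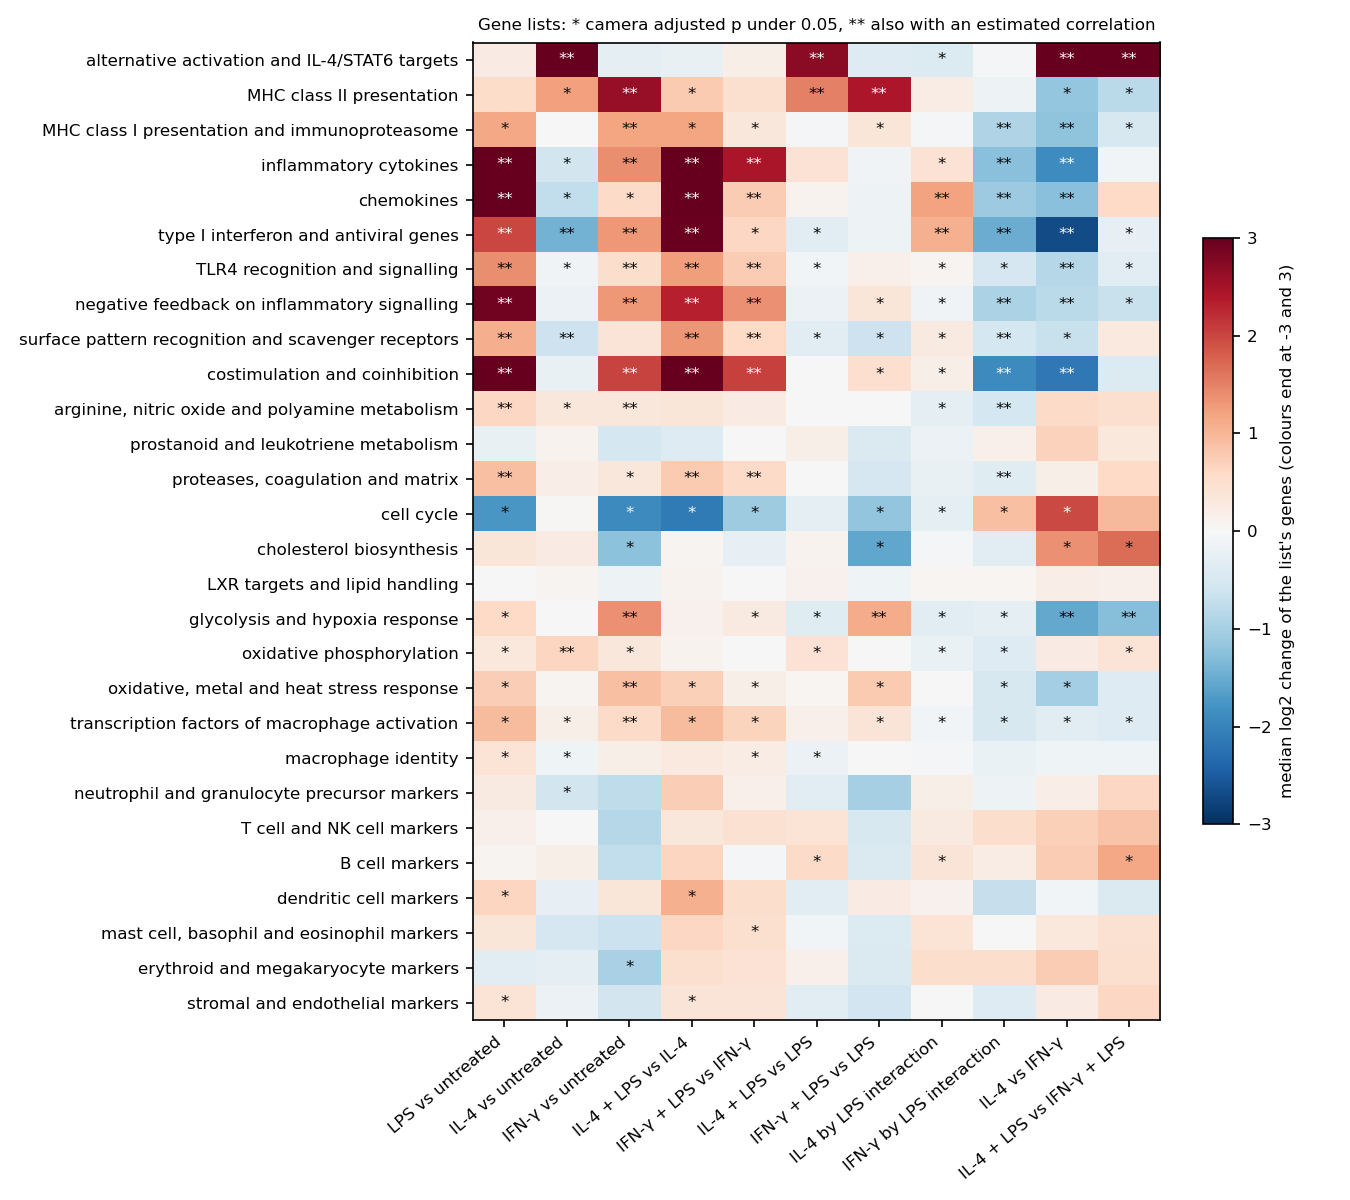
Colours give the median log2 change of each of 28 gene groups (down) in 11 comparisons (across), 1 star marks a camera adjusted p under 0.05 and 2 stars a call that also holds with an estimated correlation. Of 308 tests drawn 151 carry a star and 65 of these carry 2.

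Markers of other cell types were tested in each comparison, and none of these groups was called with an estimated correlation in the main model. Most calls were lost in further alternatives. In the macrophage identity group 12 rose and 3 fell of 24 (12 and 3 adjusted over the list alone) with LPS alone (camera adjusted p = 0.0357, and 0.494 with estimated correlation). Fcgr2b (3.39 ± 0.19) rose and Cx3cr1 (-2.42 ± 0.39) fell. The call was lost with slide as a block, at adjusted p = 0.121, and quantile normalization turned the median of 0.41 to -0.30. With IL-4 alone 2 rose and 7 fell of 24 (2 and 9 adjusted over the list alone) of that group, lost without IL-4 array B at adjusted p = 0.0995 (camera adjusted p = 0.0213, and 0.454 with estimated correlation). After LPS 0 were higher and 7 lower of 24 (0 and 7 adjusted over the list alone) with IL-4 (camera adjusted p = 2.63e-04, and 0.204 with estimated correlation). For neutrophil and granulocyte precursor markers 0 rose and 1 fell of 12 (0 and 1 adjusted over the list alone) with IL-4, a call lost with scan day as a block at adjusted p = 0.059 (camera adjusted p = 0.0291, and 0.33 with estimated correlation). With IFN-γ 0 rose and 4 fell of 12 (0 and 4 adjusted over the list alone, camera adjusted p = 0.168), called lower with slide as a block (adjusted p = 0.00108) or shared experiments (0.0482). After LPS 0 were higher and 4 lower of 12 (0 and 5 adjusted over the list alone) with IFN-γ (camera adjusted p = 0.0592), called lower in most alternatives, such as shared experiments (adjusted p = 0.0025) and normexp (0.036). Dendritic cell markers had 5 rises and 0 falls among 10 (5 and 0 adjusted over the list alone) with LPS, lost without untreated array F at adjusted p = 0.0543 (camera adjusted p = 0.0393, and 0.494 with estimated correlation). Among them were Zbtb46 (4.81 ± 0.48) and Ccr7 (2.38 ± 0.36). Stromal and endothelial markers had 4 rises and 0 falls among 11 (4 and 0 adjusted over the list alone), a call lost with scan day as a block at adjusted p = 0.05 (camera adjusted p = 0.0401, and 0.371 with estimated correlation). These included the receptor gene Pdgfrb (6.07 ± 0.37). Mast cell, basophil and eosinophil markers had 2 rises and 0 falls among 11 (2 and 0 adjusted over the list alone) with LPS after IFN-γ, lost without IFN-γ with LPS array G at adjusted p = 0.082 (camera adjusted p = 0.0221, and 0.301 with estimated correlation). An example was the histamine-forming enzyme gene Hdc (1.85 ± 0.38). Erythroid and megakaryocyte markers had 0 rises and 2 falls among 9 (0 and 3 adjusted over the list alone) with IFN-γ, not called with slide as a block at adjusted p = 0.255 (camera adjusted p = 0.023, and 0.475 with estimated correlation). B cell markers had 3 higher and 0 lower of 8 (3 and 0 adjusted over the list alone) with IL-4 and LPS against LPS (camera adjusted p = 0.0106, and 0.249 with estimated correlation). They included Cd79b (1.97 ± 0.28). This group was also called higher in the IL-4 interaction (adjusted p = 0.0175) and against IFN-γ with LPS (0.0222), as were dendritic (0.0429) and stromal markers (0.0212) with LPS after IL-4, each lost in some alternatives. MHC class II genes, which B cells share, were higher with IL-4 and LPS than with LPS too. T cell and NK cell markers had 1 rise and 2 falls among 10 (1 and 2 adjusted over the list alone) with LPS (camera adjusted p = 0.949), with a rise in Lck (5.09 ± 0.35) and a fall in Cd28 (-3.40 ± 0.37). Their median of 0.15 and mean of 0.19 stood against a lower camera rank, and the group was not called in any comparison.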

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

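The tests of slide sets and scaling behind the IFN-γ median, of the causes of the smaller LPS response after IFN-γ, of exchanges within slide sets, and of the order of the value table columns were chosen only after the result was seen.

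Among 132 combinations of a fixed gene or array measure and a group, 6 held an array far from the others of its group, and chance gives about 1 in 20. Values are log2 signal over the array's 75th percentile. In untreated array G, Arg1 was -4.61 (others -7.44 to -6.33) and Ccl24 -1.82 (others -5.13 to -3.78). In LPS array C, Irf4 was -5.96 (others -5.15 to -4.74) and Socs1 5.14 (others 6.12 to 6.68). IL-4 array C had Il10 at -2.97 (others -2.53 to -2.51) and IL-4 with LPS array G had Ccl5 at 8.78 (others 8.34 to 8.38).

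The LPS response differed after IL-4 for 356 genes. Among the genes followed, log2 differences were Cxcl10 4.58, Il12a 4.28, Ccl17 4.20, Cxcl2 4.11, Cxcl1 4.01 and Fpr2 3.47. Others were Clec4e 2.94, Rsad2 2.92, Ifit3 2.87, Ifit1 2.70, Tnf 2.54, Cd14 1.83 and Ccl5 1.30. Negative differences were Edn1 -5.95, Socs1 -4.51, Il4i1 -3.28, Klf4 -2.95 and Egr2 -2.58. Cxcl1 was well above background on no array of at least 1 group, so the size of its difference is uncertain.

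After IFN-γ the response differed for 1865 genes. Positive differences were Il23a 5.15, Fam214a 4.74, Irf4 4.47, Cnr2 4.24, Arl4c 4.20 and Stat6 0.81. Those of chemokine genes were Cxcl9 -7.42, Cxcl11 -6.03, Ccl8 -5.94, Ccl12 -4.28, Ccl5 -3.80, Cxcl10 -3.29 and Ccl17 -3.02. Other inflammatory genes were Ptgs2 -6.85, Edn1 -6.28, Il6 -6.07, Il1b -5.21, Nos2 -5.12 and Il12b -3.93. Matrix and feedback genes were Vcan -5.48, Socs1 -5.13, Socs3 -4.57 and Il1rn -3.99. Further ones were Cd40 -3.64, Cd274 -3.37, Cmpk2 -3.23, Mx1 -2.63, Irf1 -1.91, Tapbpl -1.89, Tap2 -1.81 and Irf7 -1.34. The same limit holds for Il23a and Il6.

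Splits of the arrays into groups of the same sizes were counted, with the real one. For LPS against untreated 1 of 100 splits called as many genes (9500, highest other 7841), for IL-4 1 of 100 (2531, highest other 359) and for IFN-γ 1 of 100 (5803, highest other 35). Against LPS alone, IL-4 with LPS had 1 of 100 (2011, highest other 1231) and IFN-γ with LPS 1 of 100 (5109, highest other 926). IL-4 against IFN-γ had 1 of 35 without LPS (6260, highest other 3976) and 1 of 35 with it (5736, highest other 4509). The smaller and larger LPS responses after IFN-γ had 1 of 100 (961, highest other 686). These and the interactions (2 of 100 each) are under 0.05 with slide sets ignored. With labels exchanged within slide sets the IL-4 interaction had 3 of 100 (356, highest other 1399). Slide set as a block gave 3 of 100 (1084, highest other 4059). The IFN-γ interaction had 2 of 32 (1865, highest other 2561). As a block it had 2 of 32 (4211, highest other 5862), and chance is excluded for neither interaction. The top splits exchanged all 4 (IL-4) or 3 (IFN-γ) sets without LPS and so add up effects of priming. Where letters were taken as pairs only splits that part every pair were counted, with the same counts by slide set: 8 for LPS after IL-4 (7001, highest other 0) and 4 for LPS after IFN-γ (2658, highest other 1); those that part fewer reached 1047 and 442. These splits, and the 10 for the lower and higher LPS-induced genes after IFN-γ (628, highest other 0), are too few for a share under 0.05.

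A split for the IL-4 interaction called 2427 genes (real 356). It took 4 of 4 IL-4 with LPS and 0 of 4 IL-4 arrays from slide sets 1 to 3. It kept 1 IL-4 array, so IL-4 effects enter too. One for the IFN-γ interaction called 3777 (real 1865), but it kept the 3 IFN-γ arrays and 0 of 3 with LPS, and so holds the effect of IFN-γ alone. Chance cannot be excluded for LPS-induced genes after IL-4, neither for the lower and higher genes (2 of 35 splits; real 332, highest other 1953) nor for the smaller and larger responses (7 of 100; real 165, highest other 1600). Their highest splits took 4 of 4 IL-4 with LPS and 0 of 4 LPS arrays from slide sets 1 to 3. With slide sets in place of letters and as a block, 571 genes were lower, 192 higher, 202 smaller and 249 larger. With labels exchanged only within slide sets, the lower and higher genes (763, highest other 0) have 8 splits, too few for a share under 0.05, and chance cannot be excluded for the responses (5 of 100; real 451, highest other 1293).

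The median over all genes in IFN-γ against untreated was -0.286. It was -0.066 with slide set as a block and 0.161 with median scaling, so the uneven spread of slide sets and the choice of percentile each may account for it. A biological shift of many genes was not tested and stays open.

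Of 2262 LPS-induced genes 952 had a smaller LPS change after IFN-γ. Of these 0% had a saturated spot, but milder saturation stays open. Slide sets as sole cause are argued against by 39.96% of selected genes with a smaller change when sets replaced letters. A hypothesis is that IFN-γ had already raised these genes. The IFN-γ arrays exceeded the untreated arrays A to D by a median of 1.22 over the 952 genes (886 above 0), while IFN-γ with LPS minus LPS arrays A to D had -0.23 (360 above 0), and over all 2262 genes the medians were 0.77 and -0.13. This may be inflated, since the IFN-γ arrays also enter the test and the untreated arrays A to D helped select the genes.

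Of the 28 value table columns 2 matched their own scanner file best and 26 that of another sample, 13 of them of another group, with best correlations of at least 0.9946 over probes. By scanner file labels 14 of 14 arrays with LPS exceeded every other array for Il6 (lowest 3.08, highest other -1), which argues against scanner files exchanged between groups. By column labels 0 did, so the columns of the table may be out of order. No biological explanation was tested.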

How the results depend on the processing

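The tests with slide sets (as a block, in place of letters, to divide the untreated arrays, or without set 5) with the matched value table and with letters as a block within each primed arm were chosen only after the result was seen.

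Over the alternatives 4762 of 4783 values of the 302 named gene results kept their direction and side of the threshold. Naming the largest changes made stability likely. A call was lost by 17 and gained by 4. For the 104 group results 1655 of 1750 held, 80 lost and 14 gained a call and 1 reversed. Of 653 counts 490 stayed within 1.5 times. Of the gene values 12 of the 17 lost calls came with normexp and 5 with shared experiments. Of the group losses 42 of 80 came with an estimated correlation. With 1 array or experiment left out 5425 of 5425 gene values, 1796 of 1845 group values and 655 of 723 counts stayed. The value table with columns matched to scanner files lost no named gene or group. The letter as a block within each primed arm gave 7724 genes for LPS after IL-4 and 3386 after IFN-γ and changed no call named. The cause was not tested except where fewer genes follow from the alternative itself.

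Quantile normalization reversed the median of the macrophage identity group with LPS to -0.30, and gave 3178 selected genes for IL-4 and 94 with a smaller change. The estimated correlation left 72 group calls of 162. Normexp gave 5545 genes for LPS alone, 734 for IL-4, 2682 for IFN-γ, 3568 for LPS after IL-4 and 865 for LPS after IFN-γ. Against LPS alone it gave 533 with IL-4 and 2042 with IFN-γ, for the interactions 40 and 748, and for IL-4 against IFN-γ 3065 without and 2491 with LPS. It selected 805 LPS-induced genes for IL-4 (74 lower, 27 higher, 31 smaller, 34 larger) and 1164 for IFN-γ (210 lower, 27 higher, 2 larger).

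Median scaling gave 1522 genes for IL-4, 1394 for LPS after IFN-γ, 1103 for IL-4 with LPS against LPS, and 184 and 1043 for the interactions. Shared experiments gave 1524 for IL-4, 1231 for IL-4 with LPS against LPS, 1478 for LPS after IFN-γ, 2430 for IFN-γ with LPS against LPS, and 107 and 622 for the interactions. A model of only the groups compared gave 750 for LPS after IFN-γ, 1154 for IL-4 with LPS against LPS and 2472 for IL-4 against IFN-γ with LPS.

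Slide and scan day blocks raised these counts. Slide as a block gave 11591 for LPS after IL-4, 6951 for LPS after IFN-γ, 3835 for IL-4 with LPS against LPS, and 1062 and 4153 for the interactions. Scan day as a block gave 3926 for IL-4, 5206 for LPS after IFN-γ, 3225 for IL-4 with LPS against LPS, and 905 and 3660 for the interactions. Slide set as a block gave 4522, 5939, 3753, 1084 and 4211 in the same order, and an overlap of 1195 genes in the same and 1282 in opposite directions. The experiment letter as a block lowered the larger changes after IL-4 to 68. The untreated arrays divided by letter gave an overlap of 336 and 446, and by slide set 319 and 413.

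Selection and test on all 28 arrays gave 2631 selected genes for IL-4 (553 lower, 165 smaller, 188 larger) and 378 higher for IFN-γ. Selection at log2 2 left 1576 for IL-4 (134 lower) and 959 for IFN-γ (260 lower, 92 higher, 554 smaller, 3 larger), as fewer genes pass. Slide sets in place of letters selected 2870 for IL-4. As a block they gave 571 lower, 192 higher, 202 smaller and 249 larger, and for IFN-γ 386 higher and 19 larger.

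With each array or experiment left out in turn, calls ran from 8641 to 10013 for LPS alone, 1808 to 2512 for IL-4, 3680 to 5805 for IFN-γ, 5466 to 7486 for LPS after IL-4 and 1297 to 2851 for LPS after IFN-γ. Against LPS alone they ran from 1139 to 2213 with IL-4 and 2914 to 5922 with IFN-γ. Interactions ran from 149 to 396 and 819 to 2067, and IL-4 against IFN-γ from 4397 to 6962 and, with LPS, 3837 to 6238. For LPS-induced genes after IL-4 they were 133 to 221 lower, 81 to 136 higher, 31 to 62 smaller and 61 to 119 larger. After IFN-γ these were 280 to 506, 100 to 204, 719 to 1033 and 3 to 11. Selected genes stayed at 5125 and 2262, since no selecting array was left out, and without experiment G 151 group calls were made.

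The value table as labelled was not run, because under its labels 0 of 14 LPS columns separate Il6 from the others. Signal over background limits genes near the floor. A bound is given only if no array of the lower group was well above background. Other such folds and interactions are uncertain in size.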

Other observations

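The test of experiment letters against slide sets was chosen only after the result was seen; the gene groups were fixed before.

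Of the cholesterol biosynthesis genes 0 rose and 12 fell of 25 (0 and 16 adjusted over the list alone) with IFN-γ (camera adjusted p = 4.52e-04, and 0.53 with estimated correlation). Among them was Cyp51 (-2.80 ± 0.50). After LPS 0 were higher and 16 lower of 25 (0 and 20 adjusted over the list alone) with IFN-γ (camera adjusted p = 2.75e-08, and 0.301 with estimated correlation). These included Hsd17b7 (-3.36 ± 0.67) and Idi1 (-2.86 ± 0.48). In the oxidative, metal and heat stress group 13 rose and 6 fell of 26 (13 and 6 adjusted over the list alone) with LPS (camera adjusted p = 6.16e-04, and 0.0797 with estimated correlation). Examples were the metallothionein gene Mt2 (6.55 ± 0.28) and the iron-binding lipocalin gene Lcn2 (5.92 ± 0.43). With IFN-γ 13 rose and 2 fell of 26 (15 and 3 adjusted over the list alone, camera adjusted p = 8.43e-07, and 0.014 with estimated correlation), with the amino acid stress gene Trib3 (3.57 ± 0.60). Against LPS alone, IFN-γ with LPS gave higher Trib3 (4.35 ± 0.60) and lower Mt1 (-2.97 ± 0.32) and Mt2 (-5.64 ± 0.36).

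Prostanoid and leukotriene genes moved apart in each treatment, and this group was called in no comparison of the main model. With scan day as a block it was called in IFN-γ with LPS against LPS (adjusted p = 0.0306) and in IL-4 against IFN-γ without (0.0356) and with LPS (0.0273). With LPS 6 rose and 5 fell of 18 (7 and 5 adjusted over the list alone), with a median of -0.23 and a mean of 0.94 (camera adjusted p = 0.417). Ptges (5.43 ± 0.26) and the phospholipase gene Pla2g4a (2.55 ± 0.39) rose beside Ptgs2. With IL-4 5 rose and 4 fell of 18 (7 and 4 adjusted over the list alone), Ptgs1 (4.19 ± 0.44) and the prostacyclin receptor gene Ptgir (1.70 ± 0.26) rising and the prostaglandin D synthase gene Hpgds (-1.65 ± 0.25) falling (camera adjusted p = 0.518). With IFN-γ 4 rose and 8 fell of 18 (5 and 10 adjusted over the list alone, camera adjusted p = 0.499), with falls in Alox5 (-4.80 ± 0.67) and the leukotriene C4 synthase gene Ltc4s (-3.86 ± 0.28). Of the transcription factors of macrophage activation 21 rose and 4 fell of 45 (21 and 6 adjusted over the list alone) with IFN-γ (camera adjusted p = 3.15e-07, and 0.0446 with estimated correlation), with rises in Maff (3.98 ± 0.29) and Nr4a2 (3.55 ± 0.50).

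Experiment letters and slide sets group the arrays differently. After group means were removed, arrays of the same letter correlated at a median of -0.01 over 46 pairs and arrays of the same slide set at 0.43 over 46 pairs, across genes. All 28 arrays correlated best with an array of their slide set, and 9 with an array of their letter. A hypothesis is that scanner files of untreated and LPS cells carry the letter of another experiment of the same group, so that the slide set marks the experiment. If so, the value table columns that match these files could bear the letter of the primed arrays on their slide set. They did for 12 of 12 such columns, against 2 of 12 scanner files, and 7 of 7 slide sets had 1 letter for their untreated and LPS columns. The letters do not bear on the groups, and which labels are right cannot be read from the values. In the IL-4 with LPS group 2 of 4 scanner files had the letter of the IL-4 array on their slide set.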
